A study of Mus musculus with 10 samples.

How the data were processed

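The series profiled RNA from the hippocampus of C57BL/6J mice, an inbred laboratory strain, whose mothers had a control pregnancy or were exposed to low oxygen during pregnancy (prenatal hypoxia). Each group held 5 biological replicates per the labels, and the offspring were studied as adults per the series' design text. Total RNA was extracted with TRIzol and libraries were made with the NEBNext Ultra RNA kit, per the labels' protocols. The reference was GRCm38 (mm10), per the submitters' processing notes. The aligner, the counting program, the annotation release and the strand setting were not given in the sources used here.

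The authors deposited 1 table of whole-number read counts per gene for all 10 libraries, not normalized, with 56479 gene rows. Its column names abbreviate the sample descriptions, and each column was matched to its sample by that name. No per-sample column was left unused. The identifiers in this table hold only 8 characters, so that 55573 rows carried the same Ensembl-type identifier and 906 rows carried a locus identifier beginning with XLOC, a form that transcript assembly programs use. These rows made up 56 distinct identifiers. The file does not pair its rows with gene names, and the order of the rows was not used to restore them. A gene is therefore given by its row number, counted from 1 at the first gene row, for at most 2 genes in each direction. The other genes are described by their rank in the test.

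Because of this, several analyses planned before the data were examined were not run. These were the tests of 37 gene lists (pathways, complexes, hippocampal cell types and neighbouring tissues), the values of the 3 genes in the study's title (Ythdf3, Cbln1 and Btg2), and the covariates for dissection and sex. They are not analysed here. The planned rule for named genes took the title genes, the genes past the threshold with the largest changes, and, in a direction with fewer than 5 such genes, the 5 with the smallest p. It was narrowed to the limits above after the identifiers had been seen.

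Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its default minimum count of 10, which left 16389 genes, and libraries were scaled by TMM. Groups were compared with the robust quasi-likelihood test, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. A positive log2 fold change means a higher level in prenatal hypoxia, and its SE was taken from the fold change and the F statistic. Levels are given as CPM, the counts of a gene relative to the TMM-scaled library size, and log2 CPM values carry a prior count of 2. Single values were compared between groups with two-sided exact permutation tests of the difference of means, for which 0.00794 is the smallest p that 5 against 5 libraries allow. The whole profile was tested with a one-way permutational analysis of variance (pseudo-F, Euclidean distance of log2 CPM) over all 126 splits of the 10 libraries into 5 and 5.

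The labels do not give litters, and exposure was applied to pregnancies. The p-values treat each library as independent, and pups of 1 mother would make them too small. No 2 libraries were copies of each other, as the chi-square per degree of freedom between pairs lay between 8.43 and 25.6.

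The test was checked on simulated data with the means and library sizes of the 16389 genes of this comparison. In 5 simulations with 200 changed genes each, 18% of genes changed 1.25-fold, 58% of those changed 1.5-fold, 77.2% of those changed 2-fold and 91.2% of those changed 3-fold were recovered. Of all calls, 4.83% were false, and a simulation without changes gave 1 call. Each gene and library was drawn independently, so these figures leave out variation that genes share across libraries, which the real libraries show. The Benjamini-Hochberg cutoff also loosens as more genes are called, and the simulated changes gave more calls than the 5 of the real groups. The recovered shares may therefore be too high for this comparison. Alternatives fixed before the data were examined covered size factors, library totals without the 100 most abundant genes, no filter, a filter of 1 CPM in 5 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1) with quality weights, the replicate number as a block, 1 surrogate variable (sva 3.50.0), other thresholds, and leaving out each library.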

Results

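Hippocampal transcript levels were compared between adult offspring of control pregnancies (n = 5) and of pregnancies exposed to hypoxia (n = 5), to ask how low oxygen before birth alters gene expression in the adult hippocampus. Total counts per library ranged from 16233216 to 23490765. They averaged 19007681 ± 2982882 (SD, n = 5) in controls and 18649871 ± 2907550 (SD, n = 5) in prenatal hypoxia, a difference within the spread between libraries (exact permutation p = 0.778). At least 1 read fell on 33268 rows, and 16389 genes were tested, of which 311 were XLOC loci. The biological coefficient of variation between libraries of a group was 14.1%.

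5 genes were higher after prenatal hypoxia and passed the threshold in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Among 100 randomly drawn splits of the libraries, the groups included, 5 gave at least 5 called genes, so chance was not excluded for this count. All 5 genes called for the groups carried Ensembl-type identifiers. The largest rise was in the gene in row 28424, a low-abundance transcript that went from 2.17 ± 0.807 to 7.04 ± 1.64 CPM (SD, n = 5 each; log2 fold change 1.69, SE 0.23; edgeR Benjamini-Hochberg adjusted p = 0.0161). The gene in row 23979 doubled from 13.8 ± 2.86 to 28.1 ± 4.70 CPM (SD, n = 5 each; log2 fold change 1.02, SE 0.14; edgeR Benjamini-Hochberg adjusted p = 0.0161). The next 2 by p value were more abundant and rose less. The gene ranked 3 went from 41.7 ± 7.39 to 68.9 ± 6.17 CPM (log2 fold change 0.72, SE 0.10) and the gene ranked 4 from 130 ± 22.9 to 217 ± 17.1 CPM (log2 fold change 0.74, SE 0.10), both with an edgeR Benjamini-Hochberg adjusted p of 0.0206. The gene ranked 5 went from 91.2 ± 7.49 to 122 ± 10.1 CPM (log2 fold change 0.42, SE 0.07; edgeR Benjamini-Hochberg adjusted p = 0.0492). For each of the 5 genes, all 5 prenatal hypoxia libraries lay above all 5 controls, which adds no support to calls selected for this difference.

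**Figure D1:**
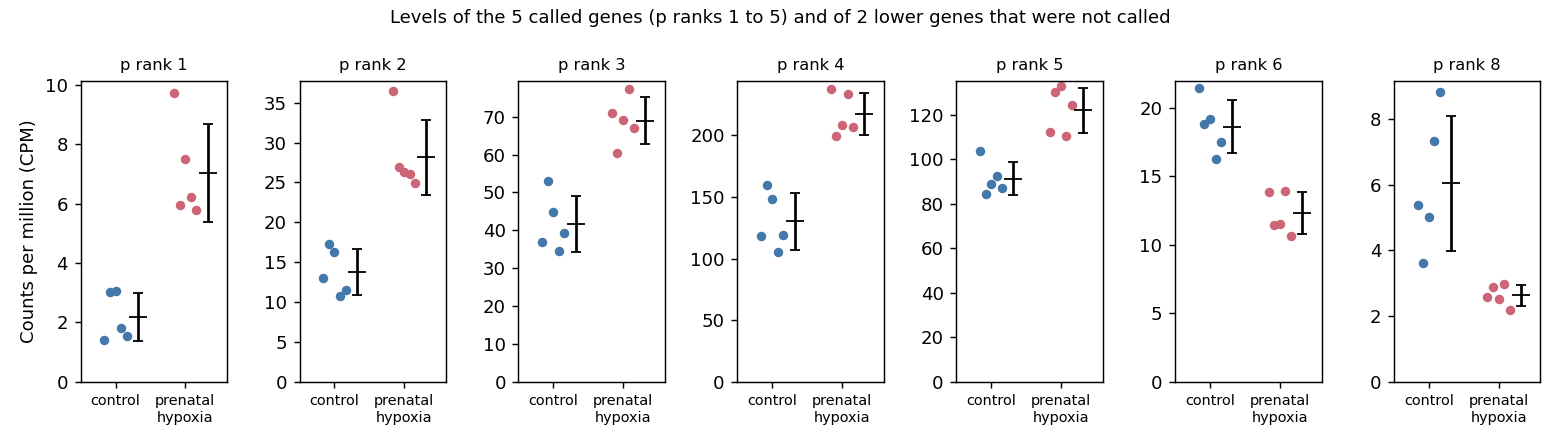
Levels (CPM) in each library for the 5 called genes (p ranks 1 to 5) and for 2 genes with lower levels in prenatal hypoxia that were not called (p ranks 6 and 8). Points are libraries, and black bars show the mean and SD of 5 libraries. In each panel the 2 groups do not overlap, from 1.41 to 3.05 CPM in controls against 5.78 to 9.72 CPM in prenatal hypoxia for rank 1.

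No gene was called lower by edgeR's quasi-likelihood test (0 genes), although 937 genes were lower at an unadjusted p under 0.05. DESeq2 called 98 lower genes and limma-voom with quality weights 2. The gene in row 29869 had 18.6 ± 1.93 CPM in controls and 12.3 ± 1.54 CPM in prenatal hypoxia (SD, n = 5 each; log2 fold change -0.60; edgeR Benjamini-Hochberg adjusted p = 0.0719). The gene in row 29216 had 6.03 ± 2.04 and 2.63 ± 0.317 CPM (SD, n = 5 each; log2 fold change -1.19; edgeR Benjamini-Hochberg adjusted p = 0.0719). Both missed the threshold, although their groups did not overlap. The gene in row 29869 passed it without prenatal hypoxia replicate 1 (edgeR Benjamini-Hochberg adjusted p = 0.0361), and the gene in row 29216 without control replicate 2 (0.0180) or control replicate 3 (0.0462). Both also passed with DESeq2 (Benjamini-Hochberg adjusted p = 0.000251 and 0.000450), and the first passed with limma-voom (0.0306). Without a filter in edgeR both passed too (0.000122 and 4.86e-06). The median prior degrees of freedom of that fit were infinite, against 9.32 in the main analysis. It thus took the variance of many genes from genes of like abundance alone, so these 2 values weigh little. The highest edgeR Benjamini-Hochberg adjusted p of the 2 genes over their alternatives was 0.238. Their log2 fold changes stayed between -0.71 and -0.55 and between -1.33 and -1.01.

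The number of called genes was small and depended on single libraries and on the test. The count of 5 went to 0 without control replicate 5 (1505 genes at an unadjusted p under 0.05) and to 0 without prenatal hypoxia replicate 3 (1263 genes). It was 2 without prenatal hypoxia replicate 5, 3 without prenatal hypoxia replicate 4, 8 without control replicate 1, 18 without prenatal hypoxia replicate 1 and 23 without control replicate 3. DESeq2 called 191 genes, 93 higher and 98 lower, and its calls included all 5 genes above. As many were called by DESeq2 in 6 of 100 drawn splits, the groups included. The gene ranked 5 was the least secure, with an edgeR Benjamini-Hochberg adjusted p from 2.97e-06, without a filter, to 0.238 over all its alternatives. Its call was also lost without control replicate 2, 3 or 4 or prenatal hypoxia replicate 2 or 5 (edgeR Benjamini-Hochberg adjusted p = 0.0541 to 0.143). It was lost too with DESeq2's size factors, with a filter of 1 CPM in 5 libraries and with 1 surrogate variable (edgeR Benjamini-Hochberg adjusted p = 0.0604, 0.0620 and 0.0719). Its log2 fold change moved little, between 0.39 and 0.47 over all 21 alternatives. Those of ranks 1 to 4 stayed at 1.54 to 1.85, 0.91 to 1.12, 0.66 to 0.82 and 0.67 to 0.82. The edgeR Benjamini-Hochberg adjusted p of ranks 1 to 4 was 0.0543 to 0.0569 without prenatal hypoxia replicate 3. It was 0.0736 to 0.103 without control replicate 5. The genes ranked 3 and 4 lost their calls without prenatal hypoxia replicate 4 or 5 (edgeR Benjamini-Hochberg adjusted p = 0.0631 to 0.0864, and up to 0.114 over their alternatives). With the replicate number as a block, the genes ranked 1 (row 28424), 3, 4 and 5 lost their calls (edgeR Benjamini-Hochberg adjusted p = 0.0682 to 0.129). Leaving out control replicates 2 and 4 and prenatal hypoxia replicate 1 together ended the calls of ranks 1 and 5 (edgeR Benjamini-Hochberg adjusted p = 0.0541 and 0.125).

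Within the groups, the levels of the 4 genes with the smallest p had positive correlations in all 6 pairs, but only some pairs passed the adjustment. After the group means were removed, the genes ranked 3 and 4 followed each other most closely across the 10 libraries (Pearson r = 0.946, Benjamini-Hochberg adjusted exact permutation p = 0.00347; Spearman rho = 0.952, adjusted p = 0.00486; r = 0.873 without the 2 libraries farthest from the median). Among the 6 pairs of these 4 genes r ranged from 0.68 to 0.95, and from 0.45 to 0.87 without the 2 farthest libraries. Of these pairs, 2 passed the adjustment over all 10 pairs of called genes for Pearson's r and 1 for Spearman's rho. The 4 pairs that included the gene ranked 5 had r between -0.66 and -0.41 and none passed.

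Differences were small over most of the tested genes. Log2 fold changes had a 5th percentile of -0.41 and a 95th of 0.41. At an unadjusted p under 0.05 there were 1966 genes (1029 higher and 937 lower), where 819 are expected on average if no gene differs. Of these 1966 genes, 396 differed at least 1.5-fold and 76 at least 2-fold (32 higher and 44 lower). Among 100 randomly drawn splits of the libraries, the groups included, 5 gave at least 1966 genes at that p, so chance was not excluded for this count. At an edgeR Benjamini-Hochberg adjusted p under 0.1 there were 15 genes, 12 higher and 3 lower, with the 5 called genes included. The share at an unadjusted p under 0.05 was 9.52% among genes of the lowest abundance, 12.3% in the middle and 14.2% among the most abundant.

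**Figure D2:**
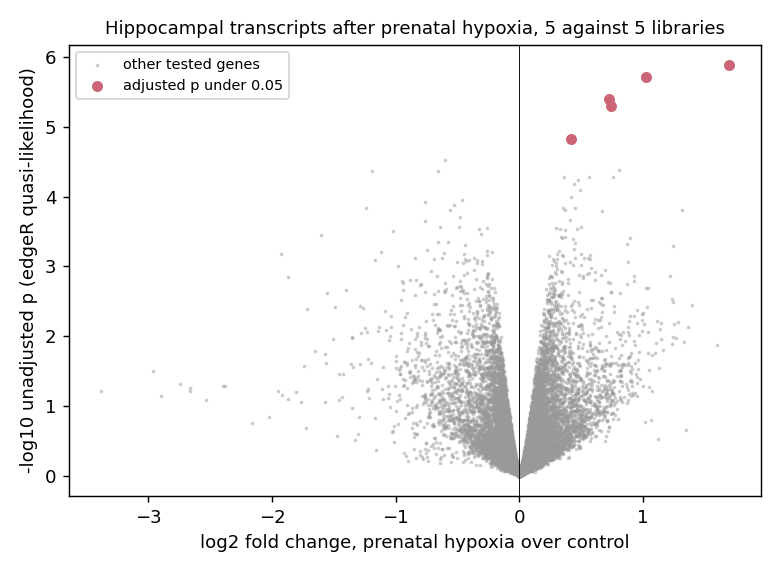
Log2 fold change of prenatal hypoxia over control (horizontal axis) against -log10 of the unadjusted p of the quasi-likelihood test (vertical axis) for 16389 genes. Red points are the 5 genes past the threshold, all with higher levels in prenatal hypoxia, and grey points are the other genes.

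XLOC loci with an unadjusted p under 0.05 were mostly higher in prenatal hypoxia, 28 against 4 lower, while annotated genes were split nearly evenly, 1001 against 933. Among annotated genes matched on abundance the numbers were 64 and 58, and the direction differed from that of the XLOC loci (Fisher's exact p = 0.000228). That test treats loci measured in the same libraries as independent, which they are not, so its p may be too small. None of the XLOC loci passed the threshold in edgeR's quasi-likelihood test (0 of 311, with 32 at an unadjusted p under 0.05). The median level of the XLOC loci relative to matched genes was -0.049 ± 0.058 log2 units in controls and 0.043 ± 0.068 in prenatal hypoxia (SD, n = 5 each; exact permutation p = 0.0476), with overlapping ranges. Higher loci outnumbered lower ones without any 1 library. Their share fell whichever library was left out, except prenatal hypoxia replicate 3 (21 against 3). It was lowest without control replicate 2 (20 against 7), followed by control replicates 3 (21 against 6), 1 (28 against 7), 4 (32 against 7) and 5 (24 against 5). The difference in level lost its side of the threshold without any 1 of control replicates 1, 2 and 4 or prenatal hypoxia replicates 2, 3, 4 and 5 (exact permutation p = 0.0714 to 0.0952).

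Across the whole profile, the groups accounted for 15.6% of the variance (pseudo-F 1.48). The median pseudo-F over the 126 splits of the libraries was 0.955 and the highest was 1.93, so much of this share comes with any split. With the groups included, 6 of the 126 splits gave a pseudo-F as large as theirs (exact permutation p = 0.0476). This side of the threshold was lost without any 1 of control replicates 1, 2, 4 and 5 or prenatal hypoxia replicates 2, 3 and 5 (exact permutation p = 0.0635 to 0.151). It was also lost with library totals without the 100 most abundant genes in place of TMM, with no filter or with the 1 CPM filter (exact permutation p = 0.0556 to 0.0794). With the trend on a set of 33 co-varying genes removed, a step chosen after seeing the data, the pseudo-F was 1.66 (exact permutation p = 0.0238). The groups did not overlap for 324 genes (163 higher and 161 lower), or 1.98% of those tested, where chance gives 0.794%. As many were found in 7 of the 126 splits (exact permutation p = 0.0556), which missed the threshold, although it was passed without control replicate 1 (exact permutation p = 0.0476) or prenatal hypoxia replicate 1 (exact permutation p = 0.0159). It was over 1.5 times larger without any 1 of control replicates 1, 3 and 4 or prenatal hypoxia replicates 1, 2 and 4 (538 to 820 genes), where 4 against 5 libraries raise the chance share to 1.59%.

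Libraries also differed along a group of genes whose levels overlapped between the groups. This set of 33 annotated genes varied together and was highest in control replicates 2 and 4 and prenatal hypoxia replicate 1. Its most variable gene ranged from 10.4 to 3576 CPM, a 343-fold span, or 89.7-fold without control replicate 5, the lowest library. The mean log2 CPM of the set was 2.25 ± 1.82 in controls and 1.54 ± 1.64 in prenatal hypoxia (SD, n = 5 each; exact permutation p = 0.540).

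**Figure D3:**
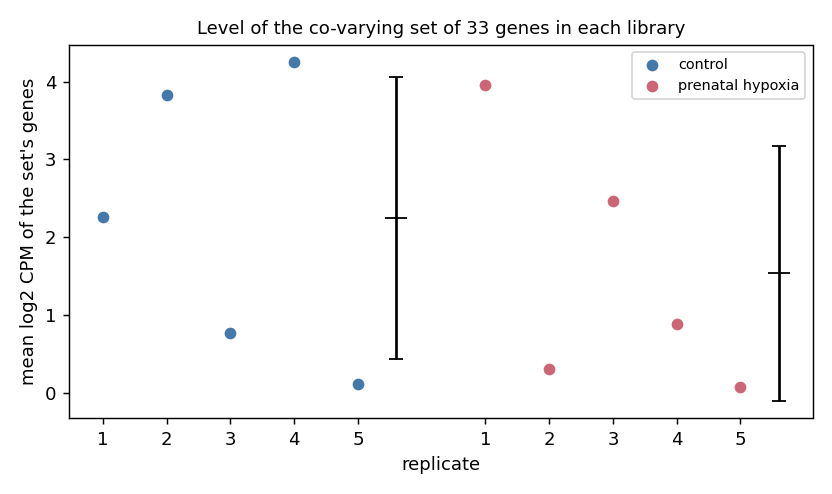
Mean log2 CPM of the 33 co-varying genes in each library, by group and replicate number. Points are libraries, and black bars show the mean and SD of each group. Values ran from 0.12 to 4.26 in controls and from 0.073 to 3.95 in prenatal hypoxia.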

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

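The outlier test and its bounds were fixed before the data were examined, and the counts of genes high in 1 library were made after the result had been seen. 2 values stood far from the rest of their group among 30 groups of 5 libraries tested. Chance alone puts 1 value apart in about 5% of groups.

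XLOC loci took 0.409% of the counts in control replicate 3, against 0.126% to 0.150% in the other controls. In the same library 10 genes of at least 5 mean CPM were more than 2-fold above every other library, and 4 of them were XLOC loci. These 10 genes took 0.802% of that library's counts and 0.037% to 0.050% in the others. The most abundant of them had 59559 reads there and 3395 to 6198 elsewhere. The abundance minimum was set after the count without it had been seen, which was 15 genes with 7 XLOC loci. Control replicate 1 had 13 such genes without the minimum and 3 with it, none an XLOC locus, and the other libraries had 0 to 6 without it and 0 with it. Over all tested genes the median log2 ratio of this library to the other controls was 0.0075, and that of XLOC loci lay 0.039 above that of annotated genes.

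The gene in row 23979, called higher in prenatal hypoxia, had 36.4 CPM in prenatal hypoxia replicate 1, against 24.9 to 27.0 CPM in the other libraries of that group. Its highest control value was 17.3 CPM, and its call held without this library.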

How the results depend on the processing

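Alternatives leaving out several libraries or using the co-varying set were chosen after seeing the data. The main analysis called 5 genes, 5 higher and 0 lower. Size factors, the 1 CPM filter, 1 surrogate variable and the set's level as a covariate each gave 4, and other library totals 5. DESeq2 called 191 genes (93 higher, 98 lower), and limma-voom with quality weights called 8 (2 lower). Without a filter the test called 444 genes (208 higher, 236 lower), of which 434 were among the genes tested in the main analysis. Its median prior degrees of freedom were infinite, against 9.32 in the main analysis. Requiring a 2-fold change left 2 genes, an adjusted p under 0.1 gave 15 and an unadjusted p under 0.05 gave 1966.

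Leaving out 1 library gave 0 to 23 genes, 0 to 13 higher and 0 to 14 lower. The counts were 0 without control replicate 5 or prenatal hypoxia replicate 3 (1505 and 1263 genes at an unadjusted p under 0.05), 2 without prenatal hypoxia replicate 5, 3 without prenatal hypoxia replicate 4, 8 without control replicate 1, 18 without prenatal hypoxia replicate 1 and 23 without control replicate 3. With the filter of all 10 libraries, leaving out prenatal hypoxia replicate 1 gave 36. Leaving out control replicate 3 and prenatal hypoxia replicate 1 together gave 106 genes (44 higher, 62 lower), including all 5 of the main analysis. Leaving out control replicates 2 and 4 and prenatal hypoxia replicate 1 gave 5 genes, of which 3 were shared. The cause was not tested in these cases, except for control replicate 3 and prenatal hypoxia replicate 1, which are taken up under the other observations.

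The replicate numbers used here are those of the sample titles, 1 to 5 in both groups, and they gave no sign of pairing the libraries. Correlations of same-numbered deviations ran from -0.16 to 0.15, and 1 of 5 controls correlated best with its own number. The sample descriptions number the controls differently, and pairing by those numbers was not tested. With the titles' replicate number as a block, 3 genes were called (1 higher, 2 lower), 1 of them shared.

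The pseudo-F was 1.47 with the other library totals (exact permutation p = 0.0556), 1.16 without a filter (p = 0.0794), 1.53 with the 1 CPM filter (p = 0.0556), 1.34 without the 3 libraries highest in the set (p = 0.114) and 1.85 without the 2 libraries left out together (p = 0.0286, the smallest that 35 splits allow). It ran from 1.21 to 1.68 without 1 library. Genes whose groups did not overlap numbered 394 to 820 without 1 library, 1265 without the 2 libraries (exact permutation p = 0.0286) and 1783 without the 3 (p = 0.0857), where fewer libraries raise the chance share to 1.59%, 2.86% and 5.71%. For the 7 genes given by row or rank, 147 refits gave 108 results on the same side of the threshold, 29 weaker, 10 stronger and 0 reversed. Dissection and sex covariates, gene lists and title genes were not run, as identifiers do not name genes. Simulated 1.5-fold changes were recovered in 58% of genes.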

Other observations

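The sets, library exchanges and XLOC comparisons below were chosen after the data had been seen. The counts over other splits, the scores and pseudo-F tests on library exchange, the test on the few libraries behind the XLOC levels, and that of library size, had bounds set before their own results were seen. The other tests were chosen after the result was seen.

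The set of 33 co-varying genes was built from its most variable member of at least 100 mean CPM, with a within-group correlation above 0.9 and an SD of at least 1 log2 unit. Both groups spanned its range (exact permutation p = 0.540). Members were chosen for a large spread within groups, so this overlap cannot decide whether prenatal hypoxia also shifted the set. The set's relation to the total count stayed under the bound of 0.65 set for library size (Spearman rho = 0.42, permutation p = 0.234). Pearson's r was 0.50 (permutation p = 0.143, Benjamini-Hochberg adjusted p of both at most 0.234) and 0.35 without the 2 libraries farthest from the median. A single RNA source carried along in different amounts is a hypothesis that stays open: the median member stepped by 2.77, 2.35, 2.21 and 0.44 log2 units where the most variable gene stepped by 2.33, 2.32, 2.63 and 0.40, but members were chosen for following that gene, so this check decides nothing. Differences between animals stay open too.

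Other splits of the libraries gave results as large as the groups did. Of 100 splits drawn at random from all 126, with the groups always included, 5 gave at least 5 genes in edgeR's quasi-likelihood test. The highest of the others gave 105. DESeq2 called 191 genes for the groups, 6 of 100 splits gave as many and the highest other gave 602. At an unadjusted p under 0.05 the groups gave 1966 genes, 5 of 100 splits gave as many and the highest other gave 2704. Chance was therefore not excluded for any of these counts. The counts with 5 of 100 lay on the 5% bound, and the splits that were not drawn could move them to either side of it. The split with 105 genes set control replicates 1 and 4 and prenatal hypoxia replicates 1, 3 and 5 against the rest. A structure of the samples that crosses the groups is a hypothesis for this split, which was the highest of those drawn, and was not tested.

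The split that exchanges control replicate 3 and prenatal hypoxia replicate 1 had the highest pseudo-F of all 126 (1.93 against 1.48) and 39 called genes. If these libraries carried each other's label, they should score on the other side of 0.5 on the 100 genes that best part the other 8 libraries (0 the control mean, 1 the prenatal hypoxia mean); control replicate 3 scored 0.704 and prenatal hypoxia replicate 1 scored 0.463, and 0.749 and 0.305 with the set's trend removed. Of 25 such pairs only this 1 crossed on both sides, and over all its partners control replicate 3 scored 0.704 to 0.881 (other controls at most 0.533) and prenatal hypoxia replicate 1 scored 0.303 to 0.543 (others of its group 0.461 to 0.983), but the pair was picked for its high pseudo-F. The axis of the co-varying set may account for it as well, since without the set's trend the pseudo-F of the labels was 1.66 (rank 3 of 126 splits, exact permutation p = 0.0238) and that of the exchanged split minus that of the labels was -0.617, though the exchanged split itself follows that axis. Single genes were mixed: of the 106 called without this pair, which include the 5 of the report, 31 put both libraries nearer the other group, 15 put both nearer their own, and 30 each did so for only 1 of them, so neither was excluded, the labels were kept throughout, and animal differences stay open.

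The excess of higher XLOC loci was not matched by annotated genes of like abundance (Fisher's exact p = 0.000228). The matched genes at an unadjusted p under 0.05 were split 64 higher and 58 lower, so no such excess was seen among them. The Fisher test treats loci as independent, so its p cannot decide whether low abundance was the cause. Loci are not independent replicates, and whether a few libraries rather than the groups carried the excess stays open: the relative XLOC level differed between groups (exact permutation p = 0.0476), but this was lost when any 1 of 7 libraries was left out (exact permutation p = 0.0714 to 0.0952). Control replicate 3 was the highest control at 0.030 and prenatal hypoxia replicate 1 the lowest of its group at -0.057. An effect of prenatal hypoxia on unannotated transcripts is a hypothesis that these libraries leave open, together with the library differences above.

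A shared factor behind the 4 called genes with the smallest p was tested with genes that followed them within groups (38 genes at a correlation above 0.8). Their median log2 fold change was 0.09, at percentile 84.7 of 1000 sets built around random genes (middle 95% from -0.17 to 0.15), with 26 of 38 higher. However, 15 of the 38 (39.5%, 12 of them higher) had an unadjusted p under 0.05 in edgeR's quasi-likelihood test, at percentile 99.9 of the same kind of sets (middle 95% from 2.81% to 30.6%), and none passed the threshold (0 of 38). Whether such a factor also differs between the groups stays open. The correlation bound was set after a stricter one had been tried.

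In 1 untested XLOC row, control replicate 1 had 410 reads and every other library at most 5. Genes more than 2-fold below every other library numbered 8 in prenatal hypoxia replicate 5, 2 each in control replicate 5 and prenatal hypoxia replicate 3, 1 each in control replicate 4 and prenatal hypoxia replicate 4, and 0 in the other libraries. The strongest had 80 reads in prenatal hypoxia replicate 5 and 659 to 1402 elsewhere.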
